A study of Mus musculus with 6 samples.

How the data were processed

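RNA was taken from microglia of Ntg and LRRK2KO mice in 3 arms (LPS for 6 h, PBS for 24 h and LPS for 24 h), with 1 array for each of the 6 groups. Total RNA was isolated with a column kit, checked on a Bioanalyser and turned into biotinylated cRNA with an Illumina amplification kit, per the labels' protocols. The labels give the Ntg strain as C57BL/6 and the LRRK2KO strain as B6.129X1(FVB)-Lrrk2tm1.1Cai/J, the age as postnatal day 3, and 1 replicate number in every group. The groups were taken from the sample titles.

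The deposited table of unnormalized values holds, per the file headers, an intensity for each of 45281 probes on each array, on a linear scale, together with a detection p-value for each probe, which the array software computes against the array's negative control beads. BeadStudio is named in the submitters' processing notes, and its version is not given in the sources used here. No intensity was below 0, so background had not been subtracted. A second deposited table, the authors' series matrix, holds intensity values that share the same quartiles on all 6 arrays, with medians of 101.16 to 101.18. Each of its columns ranked the probes as the unnormalized column of the same sample did (Spearman rho = 1), so the values are linear and quantile normalized without background subtraction, which is read from the values because the method is not given in the sources used here.

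On the arrays, 13126 to 15049 probes (29.0% to 33.2%) were detected at a detection p under 0.01. The median intensity was 100.37 (Ntg LPS 6 h), 111 (Ntg PBS), 104 (Ntg LPS 24 h), 98.2 (LRRK2KO LPS 6 h), 94.9 (LRRK2KO PBS) and 98.9 (LRRK2KO LPS 24 h). No pair of arrays shared an identical value at any probe, and the number of arrays limits the precision of every difference.

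Background was corrected by limma's neqc, using the detection p-values in place of control probes (normexp, offset 16), followed by quantile normalization and log2. Probes were named from the platform annotation: 34885 carried 1 gene symbol, 18 several and 10378 none here, and 0 symbols changed when updated through a RefSeq table of the GRCm38.p6 assembly, which served only for names and for the order of neighbouring genes. Of 15553 probes detected on at least 2 arrays, 2004 had no single gene symbol and stayed out of the comparisons. The probe with the highest mean represented a gene, which left 8598 genes, 3354 of them with over 1 detected probe and 6884 detected on all 6 arrays.

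Comparisons between arms and between genotypes came from a limma fit with genotype and arm as additive terms over all 6 arrays (lmFit and eBayes), which leaves 2 residual degrees of freedom and had 3.88 prior degrees of freedom. Errors are standard errors from the moderated variance, p-values were two-sided and adjusted by Benjamini and Hochberg over all genes tested, and an adjusted p under 0.05 counted as called. The labels list 1 array per group, so 9 differences between single arrays, within an arm or a genotype and between the responses of the genotypes, had no test. They were counted by size, as at least 2-fold with detection on the brighter array, or on at least 2 of the 4 arrays for differences of responses. Where a gene was undetected on every array of 1 side, only a bound is given: the bright side's mean against, per array, the higher of the lowest signal among detected probes and the dim probe's own, as means of normalized log2 values.

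The design, the tests, the alternatives, the rule for named genes and 27 gene lists were fixed before the data were examined. The rule took, per additive comparison, the 12 largest rises and the 12 largest falls among called genes that changed at least 2-fold, in the same direction in every genotype or arm, and were detected on every array of the higher side. For each difference between single arrays it took the 6 largest in each direction, and for each list up to 4 members with the largest change. Lrrk2, Cx3cr1, Cx3cl1, Tnf, Il1b, Il6, Nos2, Arg1 and Ptk2 were always included, and the choice of Cx3cr1, Cx3cl1 and Ptk2 may not be independent of the study's publication. The lists were cytokines, chemokines, interferon-stimulated genes, the NF-kB pathway, inflammatory enzymes, homeostatic microglia markers, receptors, alternative activation, antigen presentation, pattern recognition, lysosome and autophagy, LRRK2 relatives and partners, cell cycle, oxidative stress, glycolysis, cholesterol and lipids, oxidative phosphorylation, immediate early and heat-shock genes, sex-linked genes, chromosome 15 neighbours of Lrrk2, and markers of astrocytes, the oligodendrocyte lineage, neurons, fibroblasts and pericytes, endothelium, monocytes with border macrophages and neutrophils, and lymphocytes. Lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists within a comparison. For differences between single arrays, a list's median was placed among the medians of 10000 random lists matched on expression in 20 bins. Markers of choroid plexus and of the meninges, and pan-microglia genes, were added after the data were examined.

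The calculations ran in R 4.3.3 with limma 3.58.1 and figures in Python 3.11.15 with matplotlib 3.10.9 and pandas 2.3.3. The fit was tested on simulated data with 200 of 8598 genes changed. For LPS 24 h over PBS 24 h it recovered 50.9% of changes of 1 log2 unit, 95.7% of 2 and 100% of 3, with 7 false among 177 calls. For LRRK2KO over Ntg it recovered 72.9%, 95.5% and 97.3%, with 7 false among 186 calls. A planted list, of changed genes mixed with unchanged ones, had a camera adjusted p of 3.96e-11 and 1.06e-07 in these comparisons at the preset correlation. With an estimated correlation it was 0.562 and 0.609, so at this size the estimated version did not call a list that held truly changed genes. Noise was simulated independently for each gene and array, with variances drawn from the fit's own prior and strictly additive effects. The share of false calls in the real data, where the LPS response may depend on genotype, is therefore not shown. The simulation also cannot show how the preset version behaves where the genes of a list vary together.

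The alternatives were no background correction, an offset of 50, scaling to a common median, the authors' deposited normalized values, no filter on dim probes or other filters, the mean of a gene's detected probes, a variance trend, other size rules, and leaving out each array in turn. Leaving out both arrays of an arm was added after the data were examined. Slide was not used as a block because the files used here do not give it.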

Results

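Transcript levels were measured across the genome in microglia, the resident macrophages of the brain, isolated from mice at postnatal day 3. The Ntg mice were of the C57BL/6 strain, and the LRRK2KO mice were of the strain B6.129X1(FVB)-Lrrk2tm1.1Cai/J, in which the gene for leucine-rich repeat kinase 2 is disrupted. Cells were exposed in culture to lipopolysaccharide (LPS), the bacterial outer-membrane component sensed by Toll-like receptor 4, for 6 h or 24 h, or to phosphate-buffered saline (PBS) for 24 h. Each of the 6 combinations of genotype and arm was measured on 1 Illumina beadchip, so no group had replicates. Per array, 13126 to 15049 of the 45281 probes were detected at a detection p under 0.01, and the median intensity lay between 94.9 and 111. After normalization, 8598 genes detected on at least 2 arrays were tested.

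The layout addressed which genes respond to LPS in microglia and whether the genotypes differ. An additive limma model over the 6 arrays gave the differences between arms, averaged over the 2 genotypes, and the difference between genotypes, averaged over the 3 arms. Its error holds array noise together with any dependence of the LPS response on genotype, and the number of arrays limits its precision. Nothing in the labels says that the arrays came from separate cultures or animals, so the p-values measure only the spread between these arrays, which may be technical. Differences between single arrays had no test and are given as values. Arrays of the same arm correlated across genes at r = 0.981 for LPS 6 h, 0.983 for PBS 24 h and 0.980 for LPS 24 h between the genotypes, and all other pairs at 0.886 to 0.958. Genes are not independent replicates, so these values describe the arrays.

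Lrrk2, the disrupted gene, lay at background on nearly every array, Ntg arrays included. Of its 36 values (6 probes on 6 arrays), 1 passed detection, on the Ntg PBS array, at an intensity of 133 and a detection p of 0.00321. The Lrrk2 intensities ranged from 84.7 to 133. Lrrk2 was therefore not among the tested genes, and its level checks none of the genotype labels.

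**Figure D1:**
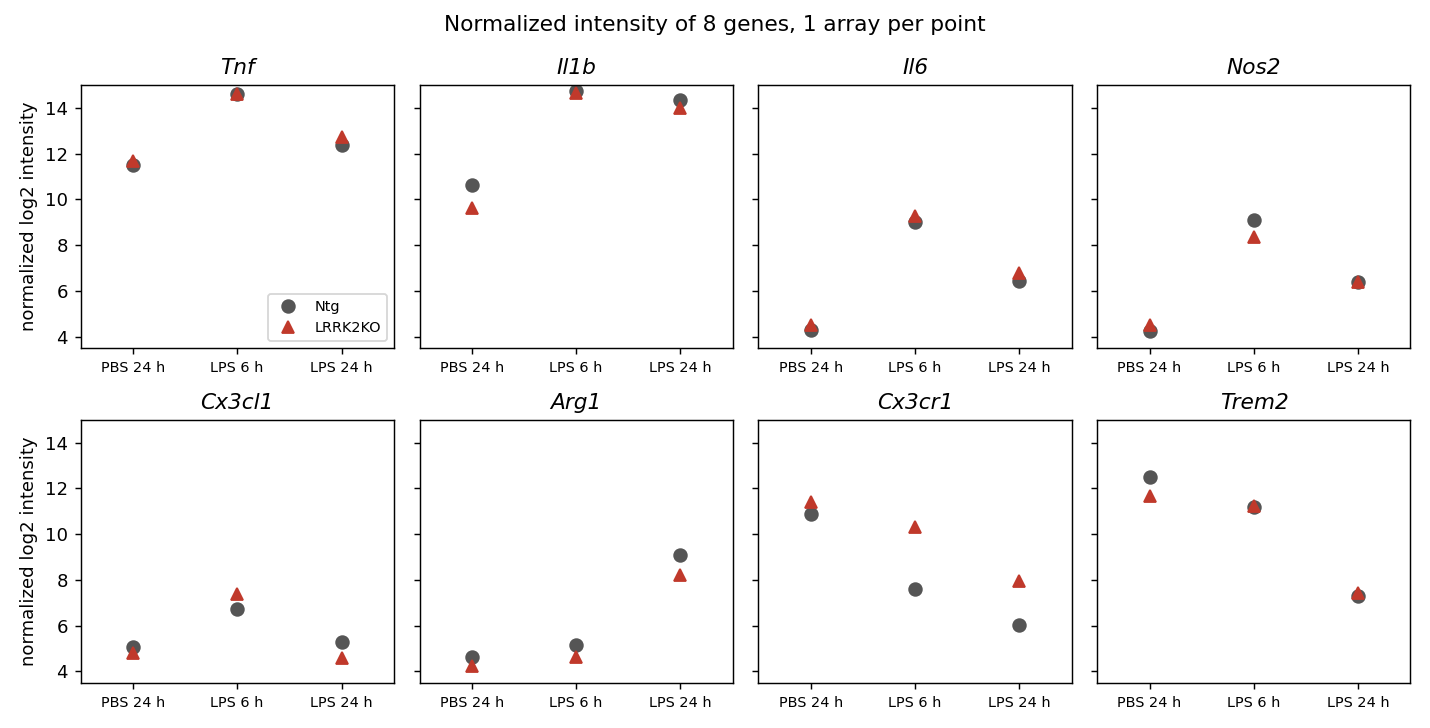
Normalized log2 intensity (vertical axis) of 8 genes in the PBS 24 h, LPS 6 h and LPS 24 h arms (horizontal axis), with 1 point per array and a separate mark for each genotype. Cx3cr1 stood at 10.87 on the Ntg PBS array and 11.42 on the LRRK2KO PBS array, and at 6.04 and 7.96 after 24 h of LPS.

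After 24 h of LPS, compared with 24 h of PBS, the largest rises were in Serpinb2, an inhibitor of plasminogen activators, Upp1, an enzyme of pyrimidine salvage, and the cytokine gene Il1a. Serpinb2 rose by 7.17 ± 0.34 on the log2 scale (SE, n = 2 arrays per arm; adjusted p = 0.000575), Upp1 by 7.15 ± 0.17 (adjusted p = 5.89e-05) and Il1a by 6.67 ± 0.39 (adjusted p = 0.0010). Il1b, which encodes interleukin-1 beta, rose by 4.03 ± 0.25 and Tnf, encoding tumour necrosis factor, by 0.97 ± 0.16 (adjusted p = 0.0010 and 0.0136). Trem2, a lipid-binding receptor of microglia, fell by 4.70 ± 0.26 on the log2 scale, and Cx3cr1, the receptor for fractalkine, fell by 4.14 ± 0.48 (adjusted p = 0.000916 and 0.00494). Cx3cl1, the fractalkine gene, differed by 0.01 ± 0.32 (adjusted p = 0.992).

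Among other genes with large rises at 24 h were the collagenase gene Mmp13 (6.28 ± 0.53), the cationic amino acid transporter gene Slc7a2 (5.49 ± 0.17), the granulocyte growth factor gene Csf3 (5.15 ± 0.31), the siderophore-binding protein gene Lcn2 (4.78 ± 0.31) and the calprotectin subunit gene S100a8 (4.57 ± 0.29). Cstdc4 and Csta2, of the stefin family, rose by 6.43 ± 0.14 and 6.09 ± 0.24, but near-identical family members may share their probes. Some genes were below detection on both PBS arrays and have only a bound: Il19 rose at least 35.3-fold, Sprr2d at least 24.0-fold, Arg1 at least 13.4-fold, Il6 at least 3.22-fold and Nos2, the inducible nitric oxide synthase gene, at least 2.76-fold. Falls also included Adssl1 (-3.88 ± 0.22), the thymidine kinase gene Tk1 (-3.60 ± 0.17), the growth factor gene Igf1 (-3.37 ± 0.20) and the replication factor gene Pclaf (-3.19 ± 0.22). Prc1 and Pbk, both mitotic, fell at least 11.1-fold and at least 7.39-fold, and Hpgd, which inactivates prostaglandins, at least 6.30-fold. The replication-dependent histone genes H2ac12 (-3.72 ± 0.15), H2ac15 (-3.71 ± 0.17) and H2ac11 (-3.39 ± 0.21) also fell, although cross-hybridization between such copies leaves the member uncertain.

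Of 32 interferon-stimulated genes tested, 22 rose and 0 fell at 24 h, against 29 and 0 adjusted over the list alone (camera adjusted p = 5.91e-17). Zbp1 (3.14 ± 0.22) and Oasl1 (2.76 ± 0.19) were among the largest. Of 16 cytokine genes 11 rose (12 adjusted over the list alone; camera adjusted p = 8.89e-10), among them Il10 (3.07 ± 0.30), and of 17 chemokine genes 9 rose (11 adjusted over the list alone; camera adjusted p = 8.79e-07), among them Ccl2 (3.64 ± 0.30) and Ccl7 (3.65 ± 0.51). Of 24 genes of the NF-kB pathway and its feedback regulators 12 rose (17 adjusted over the list alone; camera adjusted p = 4.25e-09), with Il1rn at 4.28 ± 0.32 and Socs3 at 3.93 ± 0.17. Of 18 inflammatory enzymes and acute-phase proteins 11 rose (14 adjusted over the list alone; camera adjusted p = 1.45e-09), such as Ptges (3.54 ± 0.27), the inducible prostaglandin E synthase. With an estimated correlation, each of these 5 lists had an adjusted p = 0.208.

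Cell cycle genes fell together at 24 h: 19 of 22 were lower and 0 higher, over all genes and adjusted over the list alone (camera adjusted p = 8.86e-15; adjusted p = 0.208 with an estimated correlation). Birc5 (-3.13 ± 0.17) and Top2a (-3.02 ± 0.37) were among them. Of 15 homeostatic microglia markers 8 fell and 0 rose (9 and 0 adjusted over the list alone; camera adjusted p = 1.48e-05; adjusted p = 0.208 with an estimated correlation), with Olfml3 at -2.27 ± 0.21 and Fcrls at -1.80 ± 0.20 beside Trem2 and Cx3cr1. Of 20 genes for antigen presentation 7 rose and 0 fell (12 and 1 adjusted over the list alone; camera adjusted p = 1e-05; adjusted p = 0.211 with an estimated correlation), led by H2-Ab1 (2.84 ± 0.20), a class II histocompatibility chain. Glycolysis genes rose in 6 cases and fell in 1 of 17 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00036; adjusted p = 0.279 with an estimated correlation), with the lactate transporter gene Slc16a3 at 1.51 ± 0.15. Of 15 cholesterol and lipid genes 6 fell (9 adjusted over the list alone; camera adjusted p = 0.000721; adjusted p = 0.208 with an estimated correlation), including Cyp51 (-1.47 ± 0.32) and Sqle (-1.18 ± 0.20) of sterol synthesis. Of 17 oxidative stress genes 7 fell (9 adjusted over the list alone; camera adjusted p = 0.00156; adjusted p = 0.406 with an estimated correlation), including Gclm (-1.53 ± 0.26) of glutathione synthesis.

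In all, limma called 562 genes higher and 773 lower at 24 h of LPS at an adjusted p under 0.05. Every gene named here as rising or falling moved the same way in both genotypes, which the naming rule required of the largest rises and falls. The 1335 calls became 483 without the Ntg PBS array, 595 without the LRRK2KO PBS array, 319 without the Ntg LPS 24 h array and 399 without the LRRK2KO LPS 24 h array. Of 26 lists tested by camera, 14 passed at its preset correlation and 0 with an estimated correlation.

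The 6 h response had only the 24 h PBS arrays as its reference, so treatment and culture time differed together. At LPS 6 h, Il1a stood 7.73 ± 0.39 (SE, n = 2 arrays per arm) above PBS on the log2 scale, Csf3 7.17 ± 0.31 and the stromelysin gene Mmp3 6.25 ± 0.27 (adjusted p = 0.000295, 0.000239 and 0.000239). Tnf rose by 3.01 ± 0.16 (adjusted p = 0.000301), Il1b by 4.56 ± 0.25 and Cx3cl1 by 2.11 ± 0.32 (adjusted p = 0.000337 and 0.00483). Cx3cr1 fell by 2.18 ± 0.48 on the log2 scale (adjusted p = 0.0154). Sesn1, a stress-responsive inhibitor of mTORC1 signalling, fell by 5.27 ± 0.21, and the palmitoyltransferase gene Zdhhc14 fell by 4.95 ± 0.16 (adjusted p = 0.000235 and 0.00016).

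Several rises at 6 h started below detection. Sprr2d rose at least 121-fold, Il27 at least 52.6-fold, Cxcl9 at least 45.9-fold, Il6 at least 18.7-fold and Nos2 at least 14.1-fold. Gbp5 rose at least 50-fold and Sprr2e at least 29.0-fold, but the Gbp and Sprr2 families hold close copies that may share signal. The neutrophil chemokine gene Cxcl1 (6.06 ± 0.28), Mmp13 (6.03 ± 0.53), Serpinb2 (5.53 ± 0.34) and Slc7a2 (5.53 ± 0.17) completed the largest rises. Arg1 was below background in both arms. Falls included the G1 cyclin gene Ccnd1 (-3.66 ± 0.16), the sialyltransferase gene St6gal1 (-3.55 ± 0.24), the lysosomal transporter gene Slc46a3 (-3.59 ± 0.17), the kinase gene Nuak1 (-3.45 ± 0.24) and the centromeric histone gene Cenpa (-3.29 ± 0.37). Rab3il1 fell at least 10-fold and Tk1 at least 9.77-fold.

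Of the 32 interferon-stimulated genes 31 rose at 6 h (31 adjusted over the list alone; camera adjusted p = 2.56e-20), with Oasl1 at 4.18 ± 0.19 and Mx1 at 3.98 ± 0.23. Of 16 cytokine genes 15 rose (16 adjusted over the list alone; camera adjusted p = 2.04e-13). Of 24 NF-kB pathway genes 22 rose (24 adjusted over the list alone; camera adjusted p = 6.48e-13), with Socs3 at 4.13 ± 0.17. Chemokine genes rose in 12 of 17 cases (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.73e-07), Cxcl10 among them at 5.44 ± 0.39, and pattern-recognition genes rose in 16 and fell in 2 of 26 (17 and 3 adjusted over the list alone; camera adjusted p = 2.65e-05), with the inflammasome sensor Nlrp3 at 3.04 ± 0.16. Cell cycle genes fell in 19 of 22 cases (19 adjusted over the list alone; camera adjusted p = 2.58e-08), with the replication helicase gene Mcm5 at -3.16 ± 0.18. With an estimated correlation, these 6 lists had an adjusted p = 0.209.

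Antigen presentation genes rose in 14 and fell in 1 of 20 cases at 6 h, over all genes and adjusted over the list alone (camera adjusted p = 4.73e-07; adjusted p = 0.217 with an estimated correlation), with the co-stimulatory receptor gene Cd40 at 4.32 ± 0.16. Inflammatory enzymes rose in 11 and fell in 1 of 18 (12 and 1 adjusted over the list alone; camera adjusted p = 8.36e-06; adjusted p = 0.245 with an estimated correlation), with Ptges at 4.40 ± 0.27 and Ch25h, the cholesterol 25-hydroxylase gene, at 3.83 ± 0.22. Homeostatic markers fell in 7 of 15 (9 adjusted over the list alone), a list that did not pass (camera adjusted p = 0.0644), with Selplg at -1.26 ± 0.15. Of 7 astrocyte markers 2 rose in the same comparison, with the gap junction gene Gja1 at 2.67 ± 0.21. Of 8 oligodendrocyte lineage markers 1 fell, the myelin gene Mbp (-2.90 ± 0.26). Neither list passed (camera adjusted p = 0.426 and 0.601). Fibroblast and pericyte markers rose in 1 and fell in 2 of 5 cases, and 0 of 2 neuron and 0 of 2 endothelial markers passed. Monocyte, border macrophage and neutrophil markers rose in 2 and fell in 1 of 6.

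limma called 1357 genes higher and 2256 lower at LPS 6 h than at PBS 24 h. The median of all genes was -0.13 under quantile normalization and 0.02 when arrays were scaled to a common median, which gave 1711 higher and 1769 lower. The 3613 calls became 1815 without the Ntg PBS array, 2220 without the LRRK2KO PBS array and 2384 without the Ntg LPS 6 h array.

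Between 6 h and 24 h of LPS, much of the early cytokine signal declined. Tnf fell by 2.05 ± 0.16 on the log2 scale (SE, n = 2 arrays per arm; adjusted p = 0.00272), Il6 fell by 2.54 ± 0.14 (adjusted p = 0.00172) and Il27 fell by 3.85 ± 0.17 (adjusted p = 0.00105), while Il1b differed by -0.54 ± 0.25 (adjusted p = 0.165). Trem2 fell by 3.86 ± 0.26 and Cx3cr1 fell by 1.96 ± 0.48 (adjusted p = 0.00247 and 0.0339). Arg1, the arginase gene, rose at least 11-fold, from below detection at 6 h. Sesn1 and Zdhhc14 rose by 2.92 ± 0.21 and 3.44 ± 0.16 (adjusted p = 0.00247 and 0.00105).

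Other falls over this interval included the fatty acid-binding protein gene Fabp3 (-3.99 ± 0.21), the receptor gene Ccrl2 (-3.55 ± 0.17), the phosphatase gene Dusp4 (-3.52 ± 0.20), the beta-glucan receptor gene Clec7a (-3.49 ± 0.50), Csf2 (-3.47 ± 0.15) and fibronectin, Fn1 (-3.22 ± 0.25). Rises included Gm5150 (4.42 ± 0.17), the lectin gene Cd209f (2.68 ± 0.41), the lysosomal channel gene Tpcn1 (2.58 ± 0.28) and the protease inhibitor gene Spint1 (2.42 ± 0.26), and Gstt4 and Abi3 rose at least 5.18-fold and at least 4.13-fold. Of the 32 interferon-stimulated genes 23 fell and 0 rose (27 and 3 adjusted over the list alone; camera adjusted p = 2.88e-12), including Cmpk2 (-3.42 ± 0.17) and Rsad2 (-2.66 ± 0.21). Cytokine genes fell in 12 of 16 cases (13 adjusted over the list alone; camera adjusted p = 1.28e-09), and Ifnb1, the interferon beta gene, fell at least 5.30-fold. NF-kB pathway genes fell in 12 of 24 (13 adjusted over the list alone; camera adjusted p = 2.52e-06), with Tnfaip3 at -1.69 ± 0.15, and pattern-recognition genes fell in 11 and rose in 1 of 26, over all genes and adjusted over the list alone (camera adjusted p = 0.000204), with Tlr2 at -1.44 ± 0.16. With an estimated correlation, these 4 lists had an adjusted p = 0.382.

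Oxidative stress genes fell in 7 of 17 cases between 6 h and 24 h (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000204; adjusted p = 0.432 with an estimated correlation), with the transcription factor gene Nfe2l2 at -1.54 ± 0.20. Cholesterol genes fell in 7 and rose in 2 of 15 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00385; adjusted p = 0.382 with an estimated correlation), with Cyp51 at -2.13 ± 0.32. Inflammatory enzymes went both ways, with 4 higher and 5 lower of 18 (4 and 7 adjusted over the list alone; camera adjusted p = 0.316), and Lcn2 (2.36 ± 0.31) and Mmp9 (2.07 ± 0.30) rose. limma called 1216 genes higher and 832 lower, or 1001 and 1052 with median scaling. The 2048 calls became 819 without the Ntg LPS 6 h array, 161 without the Ntg LPS 24 h array and 348 without the LRRK2KO LPS 24 h array.

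Between genotypes, averaged over the 3 arms, the largest falls on the LRRK2KO arrays were in Ttr, Wfdc2 and Ecrg4. Ttr, the transthyretin gene abundant in choroid plexus, fell by 3.25 ± 0.40 on the log2 scale (SE, n = 3 arrays per genotype; adjusted p = 0.0468), Wfdc2 fell at least 5.68-fold and Ecrg4 at least 3.63-fold (adjusted p = 0.0389 for each). Mrc1, the mannose receptor gene of border and perivascular macrophages, fell by 1.72 ± 0.15 (adjusted p = 0.0389). Rims2, encoding a presynaptic scaffold protein, rose by 3.01 ± 0.33, the transcription factor gene Sall3 by 2.45 ± 0.27 and Olfml3, a homeostatic microglia marker, by 1.5 ± 0.17 (adjusted p = 0.0389 for each). Each of the named genes that rose or fell differed in the same direction in 3 of 3 arms, which the rule for naming them required. Cx3cr1 differed by 1.73 ± 0.39 (adjusted p = 0.13), Tnf by 0.16 ± 0.13 (adjusted p = 0.595), Il6 by 0.26 ± 0.12 (adjusted p = 0.342) and Il1b by -0.49 ± 0.20 (adjusted p = 0.315), none of which passed.

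Other genes higher on the LRRK2KO arrays, all with an adjusted p of 0.0389, were Cd300ld (1.69 ± 0.14), Rbfox1 (1.61 ± 0.14), the glycine transporter gene Slc6a9 (1.56 ± 0.18), the protein kinase A subunit gene Prkar2b (1.51 ± 0.15), Rbpms (1.32 ± 0.14), Pld4 (1.26 ± 0.14), the reelin receptor gene Lrp8 (1.24 ± 0.12), Osbpl3 (1.20 ± 0.13) and Cbr3 (1.10 ± 0.13). Those lower, at the same adjusted p, were Cops8 (-1.74 ± 0.16), Cd93 (-1.60 ± 0.15), the immediate early gene Egr1 (-1.54 ± 0.16), Mndal (-1.51 ± 0.17), Gab1 (-1.47 ± 0.16) and Gm6377 (-1.38 ± 0.15), with Pcolce2 and Ntrk2 lower at least 2.73-fold and at least 2.08-fold.

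Interferon-stimulated genes were lower as a group on the LRRK2KO arrays. Of 32 tested 1 fell, Oas3 (-1.05 ± 0.13, adjusted p = 0.0437), and 23 fell adjusted over the list alone (camera adjusted p = 2.57e-16; adjusted p = 0.389 with an estimated correlation). The median differences of this list were -0.46 at PBS 24 h, -0.51 at LPS 6 h and -0.57 at LPS 24 h, each below all of 10000 random lists matched on expression. Genes of such a list may vary together, unlike those of a random list, and each arm has 1 array per genotype. These ranks therefore describe the arrays and are not a test. Of 17 chemokine genes 1 fell, and 6 fell adjusted over the list alone (camera adjusted p = 0.000885; adjusted p = 0.389 with an estimated correlation), while Ccl8 (-2.04 ± 0.32, adjusted p = 0.0739) and Pf4 (-1.93 ± 0.55, adjusted p = 0.193) did not pass over all genes. Of 20 antigen presentation genes 0 passed over all genes, and 1 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.000199; adjusted p = 0.389 with an estimated correlation). Cytokine genes numbered 0 calls of 16 (1 lower adjusted over the list alone; camera adjusted p = 0.00557; adjusted p = 0.389 with an estimated correlation).

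In the other direction, 0 of 17 oxidative stress genes passed over all genes and 9 rose adjusted over the list alone (camera adjusted p = 0.000306; adjusted p = 0.389 with an estimated correlation), with Gclm at 1.30 ± 0.22 (adjusted p = 0.0838). Of 15 homeostatic markers 1 rose, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.017; adjusted p = 0.389 with an estimated correlation). Cell cycle genes (camera adjusted p = 0.000885) and glycolysis genes (camera adjusted p = 0.000389) stood higher as lists with 0 members past the threshold over all genes, 2 and 0 higher adjusted over the list alone, and an adjusted p = 0.389 with an estimated correlation. Many cell cycle genes lay near background after LPS: their median at LPS 6 h was 0.30 as measured and 0.00 with undetected members at their bound.

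Markers of other cell types were mixed between genotypes. Astrocyte markers (0 of 7 called over all genes), neuron markers (0 of 2) and endothelial markers (0 of 2) did not pass as lists (camera adjusted p = 0.474, 0.833 and 0.679). Of 8 oligodendrocyte lineage markers 0 passed over all genes and 4 fell adjusted over the list alone (camera adjusted p = 0.0325; adjusted p = 0.573 with an estimated correlation), and their median of -0.68 became -0.29 with undetected members at their bound. Of 6 monocyte, border macrophage and neutrophil markers 1 fell, Mrc1, and 1 rose and 3 fell adjusted over the list alone, in a list that did not pass (camera adjusted p = 0.0605). Of 5 fibroblast and pericyte markers 0 passed under either adjustment (camera adjusted p = 0.037; adjusted p = 0.389 with an estimated correlation), with Dcn at -1.87 ± 0.54 (adjusted p = 0.193). Of 19 tested relatives, substrates and partners of LRRK2, 0 passed under either adjustment (camera adjusted p = 0.679), and no probe carried the symbol Ptk2 in the annotation used here.

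**Figure D2:**
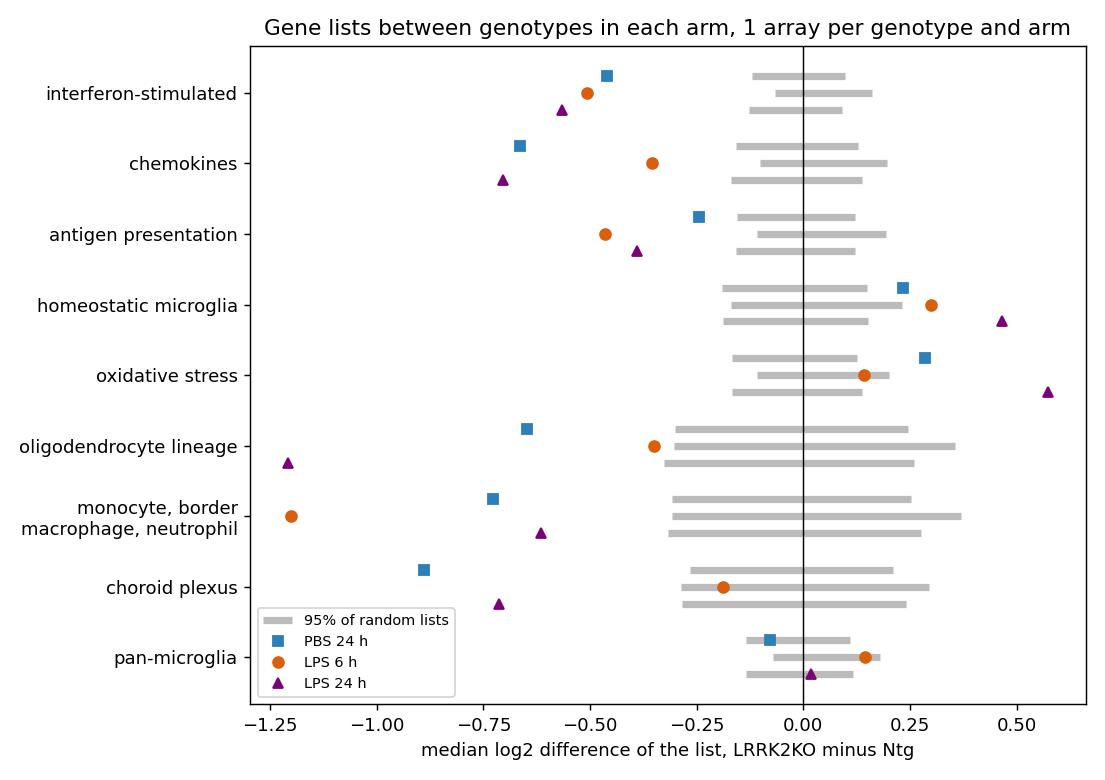
Median log2 difference, LRRK2KO minus Ntg (horizontal axis), of 9 gene lists (vertical axis) in each arm, with 1 array per genotype and arm; marks give the arm and grey bars the range of 95% of random lists matched on expression. Interferon-stimulated genes stood at -0.46, -0.51 and -0.57, left of the random range in all 3 arms, and many choroid plexus and oligodendrocyte markers were near background.

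In all, limma called 14 genes higher and 26 lower between genotypes, all at least 2-fold, and 1383 genes had an unadjusted p under 0.05. The 40 calls became 122 without the Ntg LPS 6 h array or without the LRRK2KO LPS 6 h array, 0 without either PBS array and 1 without either LPS 24 h array. Without background correction the split was 46 higher and 55 lower, and with the authors' deposited normalized values 46 and 54. Of 26 lists tested by camera, 14 passed at its preset correlation and 0 with an estimated correlation, so passing sets a list little apart. Those not named above were pattern recognition (lower, camera adjusted p = 0.0258), the NF-kB pathway (lower, 0.0398), oxidative phosphorylation (higher, 0.0478) and alternative activation (lower, 0.0496).

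Within single arms, with no test, the genotypes differed at least 2-fold at 236 genes in PBS (87 higher and 149 lower on the LRRK2KO array), 300 at LPS 6 h (148 and 152) and 338 at LPS 24 h (147 and 191). Many did not repeat: PBS shared 50 genes with LPS 6 h and 135 with LPS 24 h, and the LPS arms shared 85. Of these, 47, 134 and 84 went in the same direction. Across all genes the differences correlated at r = 0.249, 0.532 and 0.432 in the same order. In PBS, large values were in Rims2 (3.60), Slc7a11 (3.13), the cystine transporter gene, Pf4 (-3.77), encoding platelet factor 4, and Ccl7 (-3.01), with the tight junction gene Cldn11 lower at least 8.38-fold. At LPS 6 h, large values were in Cx3cr1 (2.73), Igfbp7 (2.07), Ccl8 (-2.84), Flrt3 (-2.83) and Il19 (-2.80), with Rims2 and Sall3 higher at least 6.10-fold and at least 8.5-fold and Dcn, the decorin gene, lower at least 10.6-fold. At LPS 24 h, large values were in Sprr2g (3.0), Sprr2d (2.79), Stard4 (2.19), Pla2g7 (2.14), Ttr (-4.35) and Gpx3 (-3.12), with Vcam1 lower at least 7.67-fold. Tnf differed by 0.15, -0.01 and 0.34 in PBS, LPS 6 h and LPS 24 h. With median scaling the PBS split was 115 higher and 124 lower. Without background correction, and equally with the authors' deposited normalized values, the LPS 6 h split was 30 and 58.

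The last comparison set the LPS responses of the genotypes side by side. Across the 8598 genes, the 24 h responses of Ntg and LRRK2KO correlated at r = 0.835 (rho = 0.706) and the 6 h responses at r = 0.860 (rho = 0.792). At 24 h, 892 genes differed at least 2-fold in Ntg and 847 in LRRK2KO, with 583 in both, all 583 in the same direction. At 6 h, 1999 and 1548 did, with 1151 in both and 1150 in the same direction. The Ntg 6 h split was 773 higher and 1226 lower, 981 and 997 with median scaling, and 472 and 487 without background correction or with the authors' deposited normalized values. Tnf differed from PBS by 3.09 in Ntg and 2.93 in LRRK2KO at 6 h, whereas Cx3cr1 differed by -3.27 in Ntg and -1.09 in LRRK2KO at 6 h, and by -4.83 and -3.46 at 24 h.

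**Figure D3:**
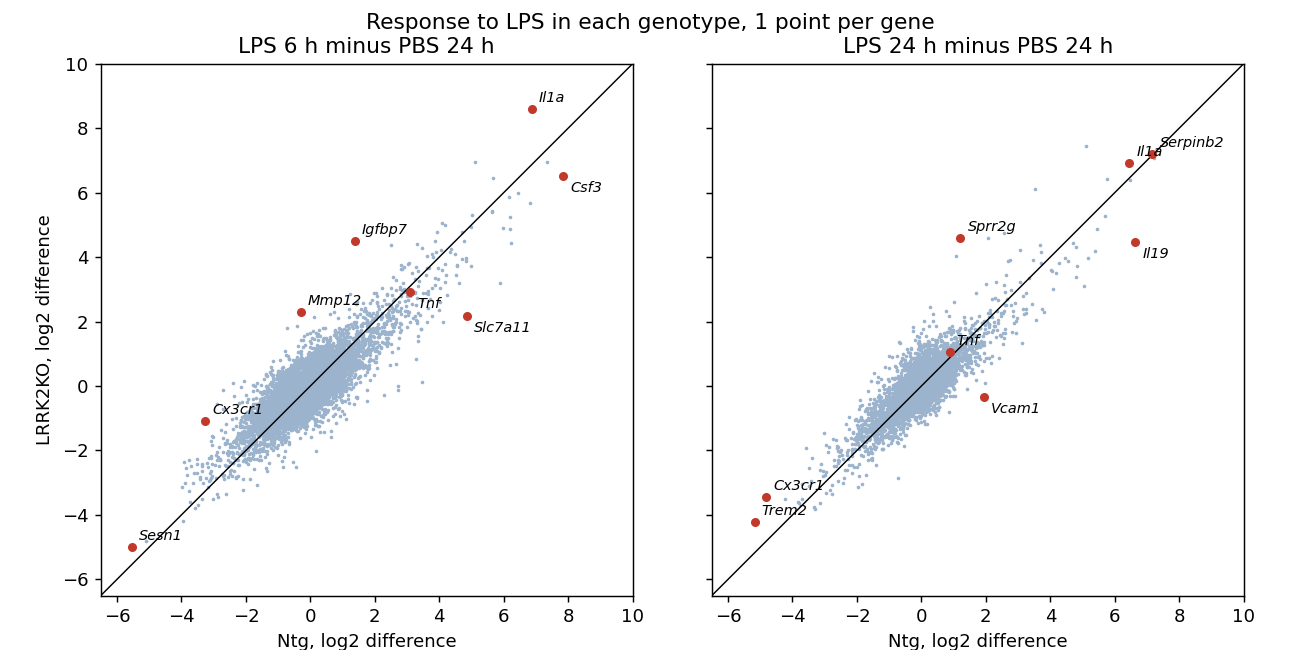
Log2 difference from PBS 24 h at LPS 6 h (left) and LPS 24 h (right), in Ntg (horizontal axis) and LRRK2KO (vertical axis), with 1 point per gene, named genes marked and a line of equality. Across genes r was 0.860 at 6 h and 0.835 at 24 h, and Cx3cr1 lay above the line at both times.

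The LRRK2KO response exceeded or fell short of the Ntg response by at least 2-fold at 227 genes at 24 h (155 with a higher response and 72 with a lower one) and 442 genes at 6 h (245 and 197). These differences between 4 single arrays had no test. At 6 h the response of LRRK2KO minus that of Ntg was 2.59 for the elastase gene Mmp12, 2.54 for Pf4, 2.27 for Clec7a and 2.18 for Cx3cr1, and -2.68 for Slc7a11, -2.58 for Sdc1 and -2.21 for Klf4. At 24 h it was 2.97 for Pf4, 2.19 for Ccl7 and 1.37 for Cx3cr1. A response difference holds the PBS difference between genotypes with its sign reversed. As given above, Pf4 and Ccl7 were already lower and Slc7a11 higher on the LRRK2KO PBS array. Their values therefore need not reflect a different response to LPS. The counts include genes undetected on up to 2 of the 4 arrays, and for such genes, among them Igfbp7, Dcn, Il19, Sprr2g, Vcam1, Cxcl9 and Il6, no exact difference is given. For Mmp13, at 2.34, 2 of 3 probes went the opposite way at 24 h. The values for Tnf were -0.16 at 6 h and 0.19 at 24 h. Both times share the PBS arrays, so they are not independent of each other. The interferon-stimulated list had a median response difference of 0.08 at 6 h and -0.05 at 24 h, inside the range of 95% of random lists. With median scaling the splits were 128 and 118 at 24 h and 191 and 238 at 6 h, and the 6 h split was 41 and 60 without background correction or with the authors' deposited normalized values.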

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

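The tests of array background, of a weaker LPS response (for Cx3cr1 and for the interferon list), of further Cx3cr1 probes and of choroid plexus RNA behind the interferon list were chosen only after the results were seen; the lists of unseen choroid plexus markers and of pan-microglia genes were written after the patterns had been seen but before their own values were.

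The 6 choroid plexus markers picked after seeing the values were lower on the LRRK2KO arrays in every arm, with Ttr at an intensity of 7646 on the Ntg PBS array and 649 on the LRRK2KO PBS array and Gpx3 at 857 and 164. A lower background of the LRRK2KO arrays is argued against for Ttr and Gpx3 by these intensities, against array medians of 111 (Ntg PBS) and 94.9 (LRRK2KO PBS). In all, 4 such genes with an Ntg intensity over 3 times the array median were at least 2-fold lower in PBS. That count is no independent support, because the markers were picked after seeing the values. Wfdc2 and Igfbp2 among them lay at 103 and 104 on the LRRK2KO PBS array, near its median. More choroid plexus cells in the Ntg cultures is a candidate source: 10 of 23 markers not seen before were tested, and 9 were lower, with a median of -0.71 against -0.20 to 0.17 for 95% of random lists and 0 called. By arm the median was -0.89 in PBS, -0.19 at LPS 6 h and -0.71 at LPS 24 h. With undetected members at their bound it was -0.54, -0.03 and -0.15, of which only the PBS value lay outside the random range of its arm. Over the arms the bounded median of -0.15 lay inside. Bounds shrink the differences of undetected members, and the random lists were not set at bounds, so lying inside their range decides nothing. This source stays open. A difference of genotype or strain in the cells themselves was not tested and stays open too.

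Cx3cr1 stood higher on the LRRK2KO arrays after LPS, by 2.73 at 6 h and 1.92 at 24 h, against 0.55 in PBS. A weaker LPS response of all genes would scale the Ntg response by the slope over all genes, 0.878 at 6 h and 0.949 at 24 h. This scaling puts Cx3cr1 at -2.87 and -4.58 in LRRK2KO, against -1.09 and -3.46 measured. The excess was 1.78 log2 units at 6 h and 1.13 at 24 h (percentiles 99.8 and 98.9). A uniform weakening of that size therefore does not give the measured values. The excess was still under 4 times its SD over all genes (0.473 and 0.397). With 1 array per group, scatter of a single gene cannot be told apart from an effect on Cx3cr1. A higher share of microglia is argued against by 21 pan-microglia genes, with a median of 0.14 and an upper quartile of 0.298 at LPS 6 h, and 0.0169 and 0.170 at LPS 24 h. An error of the single Cx3cr1 probe cannot be told apart from a difference of the transcript, because 0 further probes of the gene were detected. An effect of the genotype on the Cx3cr1 response stays open and is not an independent finding here, because Cx3cr1 was among the genes always named and was recognised as a result of the study's publication when it was picked for this section, so its percentiles may overstate how far the data alone point to it.

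Interferon-stimulated genes were lower on the LRRK2KO arrays in all 3 arms. A weaker LPS response is argued against as the cause, because the median was already -0.46 in PBS. RNA of choroid plexus cells in the Ntg cultures cannot be told apart from other sources: the median was -0.51 at LPS 6 h, where the choroid plexus markers seen before the list was written differed least (-1.37, against -2.65 in PBS and -2.88 at LPS 24 h), but 4 of these 6 markers were at a bound in every arm, with 1 pair of arrays per arm. RNA of other cell types, differences between the cultures and a lower basal interferon tone in LRRK2KO cells could each give this pattern, and none of these 3 was tested. A difference of strain was not tested either, and it goes with genotype on these arrays, so the design cannot tell them apart.

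The measured response of Fmr1nb at 6 h was 1.11 in Ntg and -1.01 in LRRK2KO, a difference of -2.12 that was not tested. None of these values is exact, since the gene was undetected on 2 of the 4 arrays, 1 in each response. It stood at 4.47 (Ntg PBS) and 4.49 (LRRK2KO LPS 6 h), below the lowest signals among detected probes there, 4.91 and 5.09. Its detected values were 5.58 (Ntg LPS 6 h) and 5.50 (LRRK2KO PBS). Against those lowest signals neither response is shown to reach 2-fold, so opposite responses are not established. Among the 2004 detected probes without a single gene symbol, outside the comparisons, 111 were at least 2-fold higher at LPS 6 h than at PBS 24 h in both genotypes.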

How the results depend on the processing

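The 3 LPS comparisons of the additive fit kept counts within 1.5 times their own under every setting of background, scaling, filter and probe choice. The 40 genes called between genotypes did not: they became 101 without background correction (31 shared), 112 with an offset of 50 (37 shared), 81 with median scaling (39 shared), 100 with the authors' deposited normalized values (31 shared), 0 with no filter on dim probes, 67 with the mean of detected probes (39 shared) and 183 with a variance trend (40 shared). The smallest adjusted p of this comparison was 0.0389, close to the threshold. The cause was not tested.

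Leaving out each array in turn gave 319 to 1633 genes for LPS 24 h over PBS 24 h, 1815 to 3325 for LPS 6 h over PBS 24 h, 161 to 1976 for LPS 24 h over LPS 6 h and 0 to 122 for LRRK2KO over Ntg. The array left alone in its arm is then assumed to vary like the others. Leaving out both arrays of an arm, chosen after seeing the data, gave 0 (PBS), 122 (LPS 6 h) and 1 (LPS 24 h) between genotypes, the same as leaving out either array, because a lone array in an arm carries nothing on the genotype. With an estimated correlation, 0 lists passed in any of the 4 comparisons, against 14, 9, 10 and 14.

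Counts by size moved too. Between genotypes, in PBS, LPS 6 h and LPS 24 h, they were 77, 88 and 107 without background correction, and the same with the authors' values, 121, 126 and 158 with an offset of 50, 142, 184 and 178 for genes detected on all 6 arrays, 867, 1218 and 1027 at 1.5-fold and 69, 49 and 88 at 3-fold. For the Ntg response at 24 h and 6 h they were 443 and 959 without background correction or with the authors' values, 590 and 1293 with an offset of 50, 2113 and 3982 at 1.5-fold and 351 and 786 at 3-fold. For the LRRK2KO response they were 373 and 716, 528 and 995, 2026 and 3365, and 314 and 605 in the same order. Response differences at 24 h and 6 h numbered 51 and 101, 86 and 184, 1050 and 1781, and 31 and 79, and 278 at 6 h for genes detected on all 6 arrays. Larger offsets and uncorrected background shrink log2 differences of dim probes by construction, and signal over background limits what these arrays resolve.

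Among named genes 1 value reversed: the Mmp13 response difference at 24 h was -0.0598 with the mean of detected probes. No paired analysis was possible because the groups share only 1 replicate number, which cannot serve as a block; the arm term of the additive fit already compares the genotypes within each of the 3 arms. Slide as a block was not run, because the files used here do not give it.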

Other observations

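The split count and the test of the genes around Lrrk2 were chosen only after the result was seen.

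The remaining gene lists were mixed at LPS 24 h over PBS 24 h, where those of alternative activation, receptors and oxidative phosphorylation did not pass. In this comparison, lysosome and autophagy genes fell in 6 of 32 cases (7 adjusted over the list alone; camera adjusted p = 0.0163; adjusted p = 0.406 with an estimated correlation), with the hexosaminidase gene Hexa at -1.18 ± 0.15. Alternative activation markers rose in 3 and fell in 4 of 11 (3 and 5 adjusted over the list alone; camera adjusted p = 0.177), with Arg1 above and the nuclear receptor gene Pparg (-2.48 ± 0.17) and Mrc1 (-2.31 ± 0.18) below. Receptors for chemokines, complement and purines rose in 2 and fell in 4 of 12 (camera adjusted p = 0.718), with the adenosine receptor gene Adora3 at 2.06 ± 0.20 and Cxcr4 at -3.02 ± 0.25. From LPS 6 h to LPS 24 h the receptor list did pass, with 5 lower and 1 higher of 12 (6 and 2 adjusted over the list alone; camera adjusted p = 0.0381; adjusted p = 0.432 with an estimated correlation). At LPS 24 h over PBS 24 h, pattern-recognition genes rose in 8 and fell in 3 of 26 (10 and 4 adjusted over the list alone; camera adjusted p = 0.0204; adjusted p = 0.279 with an estimated correlation), with Tlr13 at -2.40 ± 0.37. Immediate early and heat-shock genes rose in 2 and fell in 1 of 12 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0224; adjusted p = 0.279 with an estimated correlation), with Ier3 at 1.83 ± 0.17 and Fos at -1.53 ± 0.26. Oxidative phosphorylation genes numbered 0 calls of 22 (camera adjusted p = 0.564), and at LPS 6 h their median was -0.32 under quantile normalization and 0.04 with median scaling.

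Markers of other cell types were few after 24 h of LPS. Of 7 astrocyte markers 1 rose, Gja1 (4.05 ± 0.21), of 8 oligodendrocyte lineage markers 1 fell, Mbp (-1.14 ± 0.26), of 2 neuron markers 0 changed, of 5 fibroblast and pericyte markers 1 fell, Igfbp4 (-1.33 ± 0.24), and of 2 endothelial markers 1 fell, Egfl7 (adjusted p = 0.0439). Of 6 monocyte, border macrophage and neutrophil markers 2 rose, S100a8 and Camp (1.34 ± 0.18), and 2 fell. No lymphocyte marker was among the tested genes. Of 2 sex-linked genes Xist (-0.75 ± 0.14) fell, with 2 of its 4 probes going the other way. Between genotypes Xist differed by 0.63 ± 0.12 and Eif2s3y by -0.70 ± 0.23 (limma adjusted p = 0.0983 and 0.235 over all genes). Adjusted over the list alone, 1 was higher and 1 lower on the LRRK2KO arrays. The sex of the pups is not given in the sources used here. Meningeal markers, written after the data were examined, had a median of -0.67 between genotypes over 5 of 18 genes, and -0.05 with undetected members at their bound.

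Of the 10 splits of the 6 arrays into 3 and 3, fitted with the arm as covariate, 1 gave as many as the 40 genes called between genotypes. It was the real split itself, and the highest other gave 0. So few splits are too few for a share under 0.05. Most other splits were not balanced over the arms, and in each the genotype differences entered the error. Their 0 calls therefore decide nothing.

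Alleles of the donor strain around Lrrk2 could differ between the genotypes. Among 85 tested genes of the 100 protein-coding genes on either side of Lrrk2, 0 were called by limma, and 17.6% had an unadjusted p under 0.05 against 16.1% of other genes. The bound chosen, no call, was too weak to decide: at 3 times the rate of the other genes (0.470%) 1.20 calls would come, so a contribution of such alleles cannot be told apart from none. The 14 tested genes of the chromosome 15 list, fixed in advance, numbered 0 calls between genotypes (camera adjusted p = 0.563), and Prickle1 among them rose by 2.73 ± 0.25 after 24 h of LPS.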
